A study of Mus musculus with 22 samples.

How the data were processed

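The series holds 22 RNA-seq libraries from mouse oocytes and embryos. Each Setd2 stage had 2 control and 2 knockout libraries, and the Dnmt3l pair of full-grown oocytes had 1 of each. Libraries were assigned to groups from their titles and the column names of the tables, and no library was left out of the main comparisons. The columns of the Dnmt3l pair are named as merged, so each may combine runs or replicates.

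The authors deposited FPKM values (fragments per kilobase of transcript and per M mapped fragments) for 22592 gene symbols, and their processing notes name TopHat2 2.0.11, Cufflinks 2.0.2 and the mm9 genome without saying what each step did. Each FPKM value is used as the authors deposited it, with no count or read file. Growing oocytes, the spindle-transfer embryos and the Dnmt3l pair came in tables of their own, and full-grown oocytes, zygotes and 48 h embryos in a table of 12 libraries, so tests were made only within a table. The choice of samples, comparisons, gene lists, rule for named genes and other settings was made before the data were examined.

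Values were transformed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 2 libraries of a table were tested, which gave 10794 genes in growing oocytes, 12199 in the table of 12 libraries and 9398 in spindle-transfer embryos. A linear model with a mean for each group was fitted with limma 3.58.1 in R 4.3.3, with moderated variances and a trend of variance on mean. The 12 libraries were fitted together, so 6 groups share their spread, and contrasts gave the knockout effect at each stage, the change from zygote to 48 h in each genotype, and the differences between these effects. The p-values were two-sided, adjusted by the Benjamini-Hochberg method over all genes of a contrast, and called at 0.05. With 2 libraries against 2, the smallest p of an exact permutation test is 0.33, so no exact test of a single gene can pass and every call relies on variance shared between genes.

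Gene lists for chromatin, germ cell, embryo, housekeeping and neighbouring cell functions were tested with limma's camera with a preset correlation between genes of 0.01, and again with an estimated correlation. List members were also adjusted over the list alone. A list's counts are of its members that passed the test of single genes. Overlaps of calls were tested with a one-sided Fisher's exact test over the genes tested in both contrasts. The Dnmt3l pair was compared by log2 fold with counts and named genes taken from those with at least 10 FPKM in the higher library. List medians there took members with at least 1 FPKM in the higher library and were ranked among 10000 random lists of the same size and like mean expression.

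Named genes followed a rule: Setd2 and Dnmt3l, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM in the higher group and every knockout library on the same side of every control, and up to 4 called members of each list with the smallest adjusted p. Symbols without an established name and receptors for odorants and pheromones were left out. Where under 5 genes passed in a direction, the 5 with the smallest p there are candidates for naming as not past the threshold. For the 48 h step the 10 largest differences between genotypes each way and list members were taken, and for the Dnmt3l pair the 10 largest folds each way. Some genes that met the rule are not reported here. Where a name stands outside the rule, the text says that it was chosen after its values were seen. The symbols were matched to the GENCODE vM21 annotation of GRCm38 for transcript lengths and chromosomes only (21972 of 22592 matched), and no coordinates are given because those notes name mm9.

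Depth was not stated. The smallest step between low FPKM values of 4226 genes with a single transcript, taken as 1 fragment, gave the approximate fragments per library. In growing oocytes these were 6.17 and 5.37 M (M for mega) in controls and 5.82 and 5.37 M in the knockout. In full-grown oocytes they were 22.6 and 9.44 M, and 18 and 12.7 M. In zygotes they were 3.47 and 3.13 M, and 3.43 and 3.27 M, and at 48 h 3.35 and 3.85 M, and 4.79 and 4.84 M. In spindle-transfer embryos they were 7.76 and 6.53 M, and 6.84 and 6.1 M, and in the Dnmt3l pair 8.32 M in the control and 10.1 M in the library labelled knockout. Values under 1 FPKM rest on few fragments.

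The replicate numbers were checked as pairs by the correlation of deviations from the group means across genes. It was 0.042 in growing oocytes, 0.186 in full-grown oocytes, 0.074 in zygotes, 0.002 at 48 h and 0.072 in spindle-transfer embryos, so the numbers were not used as a block except as an alternative. The pipeline was tested on simulated data with the spread of each table and 200 changed genes. It recovered 49% of 4-fold changes in growing oocytes, 77% in full-grown oocytes, 86% in zygotes and at 48 h, 37% in spindle-transfer embryos and 41% and 40% in the tests of differences for the 48 h step and for zygotes against oocytes, with at most 11 false calls. Recovery of 2-fold changes was 3%, 21%, 28%, 30%, 0%, 2% and 5% in the order of these contrasts.

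Alternatives were a pseudocount of 0.1 or 5, no filter, a filter at 5 FPKM, scaling by median ratios, quantile normalization, no variance trend, a 2-fold threshold, a replicate block, a fit of the compared groups only, and leaving out each library in turn. Added after the data were seen were the changes from full-grown oocyte to zygote in each genotype, gene sets chosen in a control replicate and read in other libraries, list medians after quantile normalization, zygote lists without single libraries, shares of X-linked genes and other forms of the RNA mixture tests. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15. Isoforms, read coverage of deleted exons, spike-in scaling and the chromatin data of the same study could not be examined from gene-level FPKM.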

Results

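RNA-seq was made by the Smart-seq2 protocol from mouse oocytes and early embryos with and without maternal Setd2, the methyltransferase that trimethylates lysine 36 of histone H3. Growing oocytes of postnatal day 7, full-grown oocytes, zygotes, embryos at 48 h and 8-cell embryos made by spindle transfer each had 2 control and 2 knockout libraries. Full-grown oocytes of a Dnmt3l knockout and of its control had 1 library each, so that pair has no replicate error. Zygotes were collected 30 h after hCG, and the 48 h embryos are described as 2-cell for controls and 1-cell for the knockout, so that their comparison sets different cell stages side by side. The study asked in the oocytes how histone marks and transcription relate, and in the zygotes whether altered transcription passes from the mutant oocyte to the embryo.

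No read counts were given. An estimate from the smallest steps between FPKM values of genes with a single transcript put the libraries at 5.37 to 6.17 M fragments (M for mega) in growing oocytes, 9.44 to 22.6 in full-grown oocytes, 3.13 to 3.47 in zygotes, 3.35 to 4.84 at 48 h, 6.1 to 7.76 in spindle-transfer embryos and 8.32 and 10.1 in the Dnmt3l pair. It assumes that the smallest step is 1 fragment, so it is approximate, and single values near 0 carry little weight. Between 8999 and 10554 genes reached 1 FPKM in each library. Across genes, the Spearman correlation between the replicates of a Setd2 group ran from 0.934 in control spindle-transfer embryos to 0.985 in control full-grown oocytes. Values are mean FPKM ± SD (n = 2 libraries per group) unless stated, changes are log2 of FPKM + 1, which understates changes of genes near 0, and every adjusted p is from limma. The p-values measure only the spread between these libraries.

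Setd2 transcript was lower in the knockout from the full-grown oocyte to 48 h. In full-grown oocytes it stood at 4.55 ± 0.289 FPKM in controls and 0.947 ± 0.0296 in the knockout, a log2 change of -1.32 relative to the median of all genes (limma adjusted p = 0.0102). In zygotes the levels were 10.5 ± 2.33 and 1.52 ± 0.3, and Setd2 fell by 2.18 (limma adjusted p = 0.000208). At 48 h they were 48.1 ± 7.19 and 1.58 ± 0.223, and Setd2 fell by 4.68 relative to that median (limma adjusted p = 7.44e-08). Growing oocytes labelled -/- held 3.44 ± 0.329 FPKM against 5.51 ± 1.66 in those labelled +/-, a change of -0.53 that did not pass the test (limma adjusted p = 0.799). Spindle-transfer embryos labelled -/- held 16.7 ± 1.9 against 17.7 ± 0.805, a change of -0.078 (limma adjusted p = 0.934). FPKM of a whole gene does not show whether a remaining transcript still encodes the enzyme. In full-grown oocytes the Setd2 call was lost in each of the 4 fits that left out 1 oocyte library.

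**Figure D1:**
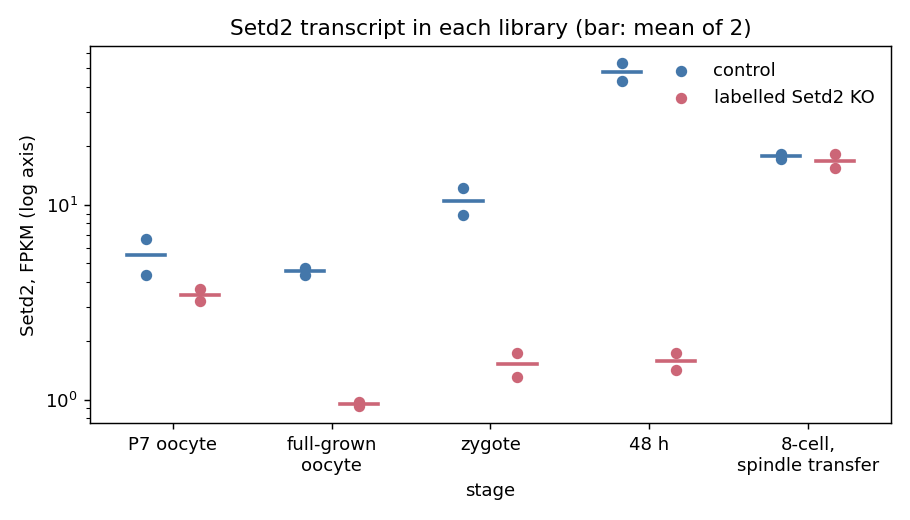
Setd2 transcript (FPKM, log axis) in each library at each stage, with controls and libraries labelled Setd2 knockout as points and the mean of 2 libraries as a bar. The groups lie apart in full-grown oocytes, zygotes and at 48 h, where the means are 48.1 and 1.58 FPKM.

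In growing oocytes of postnatal day 7 limma called 9 genes. Dcpp1 and Dcpp2, a pair of neighbouring genes known for secreted salivary proteins, rose in the knockout by 3.93 (28.5 ± 1.15 against 1.03 ± 0.888 FPKM, limma adjusted p = 0.00118) and 2.48 (47.2 ± 4.99 against 7.6 ± 0.837, limma adjusted p = 0.00118). Bglap, the bone matrix protein osteocalcin, was at 9.17 and 18.3 FPKM in the knockout libraries and listed at 0 in both controls (limma adjusted p = 0.00595). Csrp1, a LIM-domain protein of the cytoskeleton, rose by 1.66 (limma adjusted p = 0.0203), and Ccnb2, the cyclin B2 of the meiotic divisions, by 1.17 from 39.6 ± 2.47 to 90.4 ± 1.32 FPKM (limma adjusted p = 0.0373). Ier2, an immediate early gene, fell by 1.73 from 59.7 ± 14.8 to 17.7 ± 6.6 FPKM (limma adjusted p = 0.0477). Dcpp1, Dcpp2 and Bglap belong to families of near-identical genes, so the share of reads each received is uncertain.

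In total limma called 9 of 10794 genes in growing oocytes, 8 higher and 1 lower, against 868 at an unadjusted p under 0.05. With a replicate block it called 129, 54 higher and 75 lower. The falls with the smallest p that missed the threshold included Oog3, an oocyte-specific gene of the PRAME family, listed at 0 in both knockout libraries and at 6.57 ± 1.82 FPKM in controls (limma adjusted p = 0.0524). Wtap, a subunit of the complex that methylates adenosine in RNA, stood at 218 ± 17.7 against 370 ± 14.1 (limma adjusted p = 0.0847). Of the 22 gene lists tested, oxidative phosphorylation passed with a preset correlation between genes (median 0.095 over 77 members, adjusted p = 0.0305) while none of its members was called over all genes or when adjusted over the list alone, and it had an adjusted p = 0.789 with an estimated correlation. Of 41 meiosis and cell cycle genes, 1 rose (Ccnb2) and none fell, over all genes and adjusted over the list alone. Limma called 0 genes without the filter on low values (959 at an unadjusted p under 0.05) and 0 without a variance trend (825), and Csrp1, Ccnb2 and Ier2 lost their calls when single libraries were left out. The count and its direction depended on the library: 13 (4 higher, 9 lower) without knockout replicate 1, 16 (6 and 10) without knockout replicate 2, 10 (8 and 2) without control replicate 1 and 5 (5 and 0) without control replicate 2, and 16 (9 and 7) with a filter at 5 FPKM.

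In full-grown oocytes lacking Setd2 the differences lay in single genes, and no gene list passed as a set. The median change of all genes was -0.19, so changes at this stage are given relative to it, with p-values from the unshifted test. Dcpp1 rose again, by 4.50 (22.2 ± 2.94 against 0.16 ± 0.01 FPKM, limma adjusted p = 0.000911), and the protease gene Prss30 by 2.91 (5.87 ± 1.48 against 0.0324 ± 0.0458, limma adjusted p = 0.000529). Prpf39, a factor of pre-mRNA splicing, rose by 3.41 from 3.77 ± 0.543 to 43.4 ± 3.6 FPKM (limma adjusted p = 4.71e-05). Cpox, an enzyme of heme synthesis, rose by 3.11 and Hpse, which cleaves heparan sulfate, by 2.83 (limma adjusted p = 0.000743 and 0.00111). Amd2, a polyamine enzyme with a near-identical paralog, rose by 4.86 (limma adjusted p = 0.00104), and the zinc transporter gene Slc39a8 by 3.91 (limma adjusted p = 0.000743). In the knockout libraries Amd2 stood at 12.5 and 48.4 FPKM and its paralog Amd1 at 47.5 and 9.39, against 29.5 and 30.1 for Amd1 in controls. Reads may be divided between them, so the size of the Amd2 rise is uncertain. Amd1 was named after its values were seen.

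Among the falls in full-grown oocytes, Hormad1, a protein of the meiotic chromosome axis, went from 18.9 ± 5.57 to 0.213 ± 0.144 FPKM, a change of -3.82 (limma adjusted p = 0.00265). Xlr5c, of an X-linked family of nuclear proteins whose members share reads, fell by 3.06 (limma adjusted p = 0.00104). Gstp1, a glutathione transferase, fell by 2.75 from 86.8 ± 1.63 to 10.8 ± 4.11 FPKM (limma adjusted p = 0.00222). Slc9b1, a sodium-proton exchanger, fell by 2.89 (limma adjusted p = 0.000648).

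Of 42 meiosis and cell cycle genes measured in full-grown oocytes, 2 rose, 3 fell and 37 did not pass. Ccne2, the cyclin E2, rose by 2.00 from 22.3 ± 3.69 to 80.5 ± 6.17 FPKM (limma adjusted p = 0.00447), and Sycp3, of the synaptonemal complex, fell by 1.51 from 17.8 ± 2.96 to 4.75 ± 0.367 (limma adjusted p = 0.00434). Of 30 genes imprinted from maternally methylated regions, 3 rose and 27 did not pass. These were Sgce (1.76, limma adjusted p = 0.011), the organic cation transporter Slc22a3 (1.03, limma adjusted p = 0.0299) and the growth-restraining Phlda2 (1.15, limma adjusted p = 0.0364). Of 34 DNA repair genes 4 fell and none rose, among them Brca2 by 0.93, Parp1 by 1.21 and Rad50 by 0.80 relative to all genes (limma adjusted p = 0.0273, 0.0294 and 0.0378), but 1 of the 34 was called after either rescaling of the libraries. Among 28 maternal-effect genes, Smarca4, a chromatin remodeller, fell by 1.25 (limma adjusted p = 0.0253) and Khdc3, of the subcortical maternal complex, by 1.07 from 935 ± 57.5 to 396 ± 94.6 FPKM (limma adjusted p = 0.032), and 26 did not pass. Adjusted over the list alone, the higher and lower counts were 3 and 4 for meiosis, 3 and 0 for imprinted genes, 0 and 8 for repair, and 1 and 4 for maternal-effect genes.

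Dnmt3l, the cofactor that directs DNA methylation in oocytes, did not pass in Setd2 knockout oocytes (88.2 ± 13.5 against 113 ± 7.38 FPKM, limma adjusted p = 0.385). Dnmt1, the maintenance methyltransferase, and Mbd1, a reader of methylated DNA, fell by 0.81 each (limma adjusted p = 0.0368 and 0.0496), the other 15 genes of DNA methylation did not pass, and the counts adjusted over the list alone were 1 higher and 3 lower. Of 20 H3K36 methylation enzymes and readers, Morf4l1 rose by 1.43 and Zmynd11, a reader of H3K36 trimethylation, fell by 1.12 (limma adjusted p = 0.026 and 0.023), with 1 higher and 4 lower adjusted over the list alone. Of 15 H3K4 methylation enzymes limma called 0, over all genes and adjusted over the list alone. Markers of granulosa and cumulus cells, which surround the oocyte, moved apart in these libraries. Inha, the inhibin subunit, was at 15 ± 0.218 FPKM in controls and 0.668 ± 0.209 in the knockout, Cyp11a1, the first enzyme of steroid synthesis, at 2.78 ± 0.589 and 0.308 ± 0.0211, and Fshr, the FSH receptor, at 0.298 ± 0.166 and 8.87 ± 0.879. Inha fell by 3.08 and Cyp11a1 by 1.34, while Fshr rose by 3.12 (limma adjusted p = 1.5e-05, 0.00298 and 0.00171), and the other 6 of 9 measured markers did not pass (list median 0.343 relative to all genes). The list gave 2 higher and 2 lower adjusted over the list alone.

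Among 78 oxidative phosphorylation genes in full-grown oocytes 5 fell and none rose (the same counts adjusted over the list alone), Cox8a by 0.80 from 576 ± 140 to 285 ± 1.3 FPKM (limma adjusted p = 0.0187), with 1 higher and 2 lower after median-ratio rescaling. Of 51 ribosome biogenesis genes 4 fell and none rose (8 and 1 adjusted over the list alone), with 2 higher and 2 lower after that rescaling.

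By limma, 844 of 12199 genes were called in full-grown oocytes, 247 higher and 597 lower, and none of 24 lists passed as a set (3014 genes had an unadjusted p under 0.05). With the compared groups alone it called 2787, 716 higher and 2071 lower. Rescaling by median ratios moved the median of all genes to -0.026 and the split to 391 higher and 323 lower, and quantile normalization to -0.014 and to 401 and 298, so 54.8% or 57.4% of calls were higher in place of 29.3%. Of the growing-oocyte calls, Dcpp1 and Dcpp2 were again higher, a pair of neighbouring paralogs that share reads and so count as close to 1 gene. Each library mattered: 43 genes were called without knockout replicate 1, 145 without knockout replicate 2, 84 without control replicate 1 and 50 without control replicate 2. Of the 61 calls made for genes chosen by rule, 15 held in all 4 of these fits, among them Dcpp1, Prss30, Prpf39, Cpox, Hpse, Amd2, Slc39a8, Fshr, Hormad1, Xlr5c, Gstp1, Slc9b1, Inha and Cyp11a1. The others named at this stage did not, and Dnmt1, Khdc3, Brca2, Rad50 and Mbd1 also lost their calls after median-ratio rescaling.

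In zygotes from Setd2 knockout oocytes, most ribosomal protein and respiratory genes and some genes of egg proteins had higher FPKM than in control zygotes. FPKM values are shares within a library, so amounts per zygote were not measured. Mos, the kinase that holds the egg in meiotic arrest, stood at 859 ± 19.9 FPKM against 36.9 ± 11.3 and rose by 4.54 (limma adjusted p = 2.15e-06). Zp3, a protein of the egg coat, rose by 3.35 from 163 ± 4.91 to 1820 ± 1010 FPKM (limma adjusted p = 8.35e-05), and H1foo, the linker histone of oocytes, by 1.75 from 2510 ± 289 to 8440 ± 1310 (limma adjusted p = 0.000363). H2afx, the histone variant phosphorylated at DNA breaks, rose by 4.23 from 30.4 ± 6.42 to 581 ± 12.1 FPKM (limma adjusted p = 2.15e-06). Hormad1 and Xlr5c were low here too, at 0.101 ± 0.144 against 13.5 ± 2.32 and 0.139 ± 0.197 against 20.6 ± 1.23 FPKM, falls of -3.71 and -4.26 (limma adjusted p = 0.00052 and 3.97e-05).

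Of 79 ribosomal protein genes measured in zygotes, 53 rose, 1 fell and 25 did not pass, with a median of 1.69, and adjusted over the list alone 59 rose and 1 fell. Rpl5 rose by 3.72 from 2.26 ± 0.274 to 43.3 ± 16.1 FPKM and Rps2 by 2.73 from 10.9 ± 0.0122 to 78.4 ± 7.63 (limma adjusted p = 2.66e-05 and 3.97e-05). Of 78 genes of oxidative phosphorylation, 53 rose and 2 fell (54 and 4 adjusted over the list alone), with a median of 1.25. Uqcrc1, of respiratory complex III, rose by 3.91 and Atp5o, of the ATP synthase, by 4.19 (limma adjusted p = 7.15e-05 and 9.21e-05). Of 36 proteasome genes, 15 rose and none fell (16 and 0 adjusted over the list alone), with a median of 0.61, and Psmd7 rose by 1.69 from 42.8 ± 5.13 to 140 ± 5.37 FPKM (limma adjusted p = 0.000112). These 3 lists passed as sets with a preset correlation (adjusted p = 2.99e-16, 3.1e-11 and 0.000685), and each had an adjusted p = 0.951 with an estimated correlation. Genes called higher had a shorter median transcript (2466 nt) than genes called lower (3703 nt), and the members of the ribosomal protein list are short (median 1059 nt). The replicates of knockout zygotes differed in these lists: the median of ribosomal proteins was 1.32 without knockout replicate 2 (45 higher) and 2.18 without replicate 1 (65 higher), and that of oxidative phosphorylation 0.846 (30 higher) and 1.77 (58 higher). The proteasome count was 9 without knockout replicate 2 or without control replicate 1.

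Oocyte growth and identity genes in zygotes gave 10 higher and 1 lower of 26 (10 and 3 adjusted over the list alone), among them Zp3, Zp1 at 554 ± 209 against 83.6 ± 1.83 FPKM, and H1foo. The stress response gave 10 higher and 3 lower of 24 (the same counts adjusted over the list alone), with the chaperone gene Hspa8 up by 2.48 from 70.5 ± 14.5 to 405 ± 140 FPKM (limma adjusted p = 0.000103) and Ddit3 up by 1.75 (limma adjusted p = 0.00352). Without knockout replicate 2 the stress response had 3 higher members. Splicing genes split, with 9 higher and 7 lower of 38 (10 and 7 adjusted over the list alone), Snrpd2 rising by 5.06 from 1.94 ± 0.141 to 102 ± 44.2 FPKM and Snrpf falling by 1.22 (limma adjusted p = 5.13e-05 and 0.00122). None of these 3 lists passed as a set.

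Chromatin genes moved in both directions in knockout zygotes. Of 15 H3K4 methylation enzymes, 5 fell and none rose, over all genes and adjusted over the list alone, including the methyltransferase genes Mll2 (a change of -1.29) and Mll3 (-1.17) and the demethylase gene Kdm1a (-1.70), with limma adjusted p = 0.00885, 0.0119 and 0.00931. The list did not pass as a set in limma's camera test (adjusted p = 0.117), and 0 of its members were called without knockout replicate 2 or without control replicate 1. Of 13 Polycomb and H3K27 genes 1 rose and 3 fell, and of 20 H3K36 methylation enzymes and readers 2 rose and 3 fell (1 and 3, and 2 and 2, adjusted over the list alone), and neither passed as a set (limma's camera, adjusted p = 0.313 and 0.378). Suz12, a core subunit of Polycomb repressive complex 2, fell by 1.78 from 65.2 ± 29.3 to 17.4 ± 2.51 FPKM (limma adjusted p = 0.00209), and Ezh2, its catalytic subunit, by 1.01 (limma adjusted p = 0.0075, lost without control replicate 1), while Rnf2, of Polycomb repressive complex 1, rose by 0.84 (limma adjusted p = 0.0159). Nsd1, another H3K36 methyltransferase, fell by 1.11 from 16.6 ± 0.764 to 7.26 ± 1.53 FPKM (limma adjusted p = 0.00478), while Morf4l1 and Setmar rose by 0.95 and 1.28 (limma adjusted p = 0.0222 and 0.0257). Tet2, which oxidizes methylated cytosine, rose by 1.24 (limma adjusted p = 0.00599). Genes imprinted from maternally methylated regions gave 6 higher and 2 lower of 30, over all genes and adjusted over the list alone, with Phlda2 up by 1.44 from 26.9 ± 0.49 to 74.5 ± 0.539 FPKM (limma adjusted p = 0.00149). Sgce was at 1.37 ± 0.073 FPKM in the knockout and listed at 0 in both controls (limma adjusted p = 0.00612).

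Limma called 3850 genes in zygotes, 2255 higher and 1595 lower, with 5221 at an unadjusted p under 0.05. With the compared groups alone it called 2607, 1721 higher and 886 lower, fewer than the 2787 in full-grown oocytes fitted that way. Quantile normalization gave 1968 higher and 2233 lower, so that 46.8% of calls were higher in place of 58.6%. The count was 2256 without knockout replicate 2 and 2489 without control replicate 1. Genes called in full-grown oocytes were often called in zygotes in the same direction: 186 higher, where independent calls would share 45.7, and 276 lower, where they would share 78.1 (one-sided Fisher p = 3.77e-86 and 3.12e-93). Genes are not independent replicates, and both calls come from the same fit. Of the oocyte calls, 9 higher ones were called lower in zygotes and 39 lower ones were called higher.

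The Setd2 effect itself differed between zygotes and full-grown oocytes for 1145 genes by limma's test of the difference, 1011 in the upward direction and 134 downward. The median of all genes in this test was 0.195, and medians here are relative to it. Ribosomal proteins gave 46 upward and none downward of 79 (58 and 2 adjusted over the list alone), with a median of 1.83, and oxidative phosphorylation 39 and none of 78 (56 and 0 adjusted over the list alone), with a median of 1.45. Ribosome biogenesis gave 13 upward of 51 and none downward (19 and 0 adjusted over the list alone), and proteasome genes 10 of 36 and none downward (12 and 0 adjusted over the list alone). These lists had an adjusted p = 1.22e-18, 9.41e-16, 0.0015 and 0.000414 with a preset correlation, and an adjusted p = 0.675, 0.675, 0.675 and 0.681 with an estimated correlation. Downward sets in limma's camera test were Polycomb genes with 0 upward and 1 downward of 13 (adjusted p = 0.014), RNA decay genes with 2 and 2 of 26 (adjusted p = 0.0227) and 2-cell markers with none called of 35 (adjusted p = 0.0311), the same counts adjusted over each list alone. These sets had an adjusted p = 0.675, 0.675 and 0.925 with an estimated correlation, and the 2-cell markers lost their call after median-ratio rescaling. That rescaling gave 657 upward and 202 downward genes (76.5% upward in place of 88.3%) and quantile normalization 671 and 310 (68.4%). The count was 1964 without knockout zygote replicate 1, 668 without its replicate 2, 716 without control zygote replicate 2, 341 and 743 without knockout oocyte replicates 1 and 2, and 545 and 320 without control oocyte replicates 1 and 2.

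At 48 h, FPKM of egg genes was far higher in knockout embryos described as 1-cell than in 2-cell controls. That of 2-cell activation and ribosome genes was far lower. The median change of all genes was 0.43, and changes at 48 h are relative to it. H1foo stood at 7870 ± 1710 FPKM against 34.2 ± 2.47 and was higher by 7.36 (limma adjusted p = 1.13e-09). Zar1, an egg protein needed after fertilization, was at 1550 ± 404 against 7.94 ± 0.495 and Mos at 705 ± 76.1 against 3.26 ± 0.221 FPKM, higher by 6.98 and 6.94 (limma adjusted p = 8.31e-09 and 1.13e-09). Lower in the knockout were Spic, a transcription factor, at 0.273 ± 0.385 against 1600 ± 200 FPKM, the metallothionein gene Mt1 at 2.53 ± 0.357 against 3390 ± 153, and Obox6, a homeobox gene of the activated embryo with close paralogs, at 1.67 ± 1.16 against 1280 ± 7.69. Their changes were -10.76, -10.34 and -9.41 (limma adjusted p = 9.36e-10, 4.22e-09 and 2.68e-09).

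Of 26 oocyte growth and identity genes, 25 were higher in knockout embryos at 48 h and 1 was lower, with a median of 4.79, and the same counts adjusted over the list alone. Dazl, which regulates translation in germ cells, was at 443 ± 5.5 against 5.06 ± 0.36 FPKM (limma adjusted p = 1.13e-09). Of 28 maternal-effect genes, 21 were higher and 4 lower (the same counts adjusted over the list alone), with a median of 1.81, and Nlrp5 stood at 309 ± 55.6 against 12.8 ± 0.0828 FPKM (limma adjusted p = 2.33e-08). Of 35 markers of 2-cell activation, 28 were lower and 2 higher (the same counts adjusted over the list alone), with a median of -2.46, among them Tdpoz4 at 0.313 ± 0.143 against 27.8 ± 1.87 FPKM. Of 51 ribosome biogenesis genes, 42 were lower and 1 higher (43 and 1 adjusted over the list alone), with a median of -2.76, and Nop16 stood at 0.247 ± 0.349 against 255 ± 6.8 FPKM (limma adjusted p = 1.38e-08). Of 79 ribosomal protein genes, 73 were lower and none higher (74 and 0 adjusted over the list alone), with a median of -2.64, and Rpl19 stood at 22.1 ± 8.35 against 353 ± 43.1 FPKM (limma adjusted p = 4.61e-07). In the order given, these 5 lists had an adjusted p = 1.06e-08, 0.00274, 2.18e-07, 1.11e-11 and 1.43e-13 with a preset correlation. They had an adjusted p = 0.0845, 0.694, 0.659, 0.26 and 0.659 with an estimated correlation.

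Genes of epigenetic control at 48 h differed in both directions. Dnmt1 was at 89.1 ± 0.645 FPKM in the knockout against 7.74 ± 0.211, and Tet3, which oxidizes methylated cytosine in the zygote, at 49.2 ± 1.92 against 2.42 ± 0.105, higher by 2.94 and 3.44 (limma adjusted p = 3.43e-07 and 2.8e-07). Dnmt3l was at 74 ± 6.4 against 9.56 ± 0.0615 FPKM (limma adjusted p = 1.05e-06), and 10 of 17 DNA methylation genes were higher and 4 lower, over all genes and adjusted over the list alone. Kdm5a, an H3K4 demethylase, was at 0.317 ± 0.0195 against 13.2 ± 0.185 FPKM and Kdm4c, which demethylates H3K9 and H3K36, at 0.0715 ± 0.0327 against 24.9 ± 2.61, changes of -3.86 and -5.02 (limma adjusted p = 2.85e-08 and 4.22e-09). Pluripotency genes gave 3 higher and 9 lower of 16 (the same counts adjusted over the list alone), and Dppa4 stood at 4.61 ± 2.3 against 566 ± 14.2 FPKM. Of 16 p53 response genes, 5 were higher and 6 lower (the same counts adjusted over the list alone), and Cdkn1a, the p21 inhibitor, stood at 0.779 ± 0.462 against 18.2 ± 4.22 FPKM (limma adjusted p = 1.07e-06). Neither of the last lists passed as a set.

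In all, limma called 8997 of 12199 genes at 48 h, 5270 higher and 3727 lower (9231 at an unadjusted p under 0.05). The median of all genes was 0.12 after median-ratio rescaling and 0.152 after quantile normalization, with 50.3% and 51.6% of calls higher. Without any 1 library the count stayed between 7142 and 8340. Of the genes called higher in zygotes, 1089 were also called higher at 48 h, where independent calls would share 974 (one-sided Fisher p = 3.97e-08), and 663 were called lower. Of those called lower in zygotes, 357 were lower again, where 487 would be shared by independent calls (one-sided Fisher p = 1), and 727 were higher.

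From zygote to 48 h, egg transcripts fell and those of ribosomes and 2-cell markers rose in control embryos, while no member of these lists was called in knockout embryos. In controls the median change of all genes was -0.34, and changes are relative to it. In controls H1foo fell by 5.81 from 2510 ± 289 to 34.2 ± 2.47 FPKM, and Btg4, an adaptor of maternal RNA decay, by 5.14 from 3360 ± 261 to 74.9 ± 12.3 (limma adjusted p = 3.31e-09 and 4.09e-09). Obox6 rose by 10.21 from 0.372 ± 0.199 to 1280 ± 7.69 FPKM, and Rps19 by 7.90 from 0.648 ± 0.0471 to 310 ± 0.992 (limma adjusted p = 1.81e-09 and 7.32e-09). In knockout embryos H1foo went from 8440 ± 1310 to 7870 ± 1710 FPKM, Btg4 from 2430 ± 572 to 2230 ± 80.7 and Rps19 from 21.4 ± 11.8 to 24.9 ± 5.74, and none of the 3 was called.

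In controls all 79 ribosomal protein genes rose (median 4.79), 46 of 51 ribosome biogenesis genes rose and 1 fell, and 30 of 35 2-cell markers rose and 4 fell. Oxidative phosphorylation gave 52 higher and 8 lower of 78, and proteasome genes 24 and 5 of 36. Oocyte growth and identity genes gave 1 higher and 24 lower of 26 (median -3.81), maternal-effect genes 5 and 20 of 28, and RNA decay genes 4 and 19 of 26. Adjusted over the list alone, ribosome biogenesis had 47 and 1, proteasome genes 24 and 6, and the other 6 lists the same counts. With a preset correlation the 8 lists had an adjusted p = 2.86e-20, 1.24e-11, 5.17e-07, 4.34e-06, 0.00155, 3.14e-07, 0.00206 and 0.0145 in the order given. They had an adjusted p = 0.482, 0.262, 0.6, 0.773, 0.757, 0.135, 0.6 and 0.6 with an estimated correlation. In knockout embryos no member of these lists was called between zygote and 48 h, where limma gave 25 genes in total and 1240 at an unadjusted p under 0.05. As sets, 2-cell markers (median 0.64), ribosomal proteins (0.36) and oxidative phosphorylation (0.30) passed there with a preset correlation (adjusted p = 8.95e-06, 0.00136 and 0.000121), with 1, 0 and 2 members higher when adjusted over the list alone, and each had an adjusted p = 0.977 with an estimated correlation.

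Limma's test of the difference between genotypes called 8079 genes for the step from zygote to 48 h, 4480 with a more positive and 3599 with a more negative change in the knockout. The median of all genes was 0.36, and values here are relative to it. Zar1 differed by 6.43 and Dazl by 5.75 (limma adjusted p = 5.41e-07 and 5.49e-08), and Crxos1, a homeobox gene, by -10.67 and Obox6 by -9.32 (limma adjusted p = 2.76e-08 and 1.18e-07). In limma's camera test, ribosomal proteins gave 77 of 79 more negative and none more positive (adjusted p = 4.58e-20), ribosome biogenesis 43 and 1 of 51 (adjusted p = 1.32e-11), 2-cell markers 25 and 4 of 35 (28 and 4 adjusted over the list alone, adjusted p = 6.32e-06), oxidative phosphorylation 42 and 9 of 78 (43 and 9 adjusted over the list alone, adjusted p = 0.000191) and proteasome genes 22 and 4 of 36 (adjusted p = 0.00376). More positive by limma's camera were 23 of 26 oocyte identity genes and 1 more negative (24 and 1 adjusted over the list alone, adjusted p = 4.76e-08), 21 and 4 of 28 maternal-effect genes (adjusted p = 0.000813) and 17 and 4 of 26 RNA decay genes (adjusted p = 0.0117). Where no other count is given, adjusted over the list alone the counts were the same. In the order given, the lists had an adjusted p = 0.489, 0.263, 0.604, 0.708, 0.708, 0.103, 0.604 and 0.604 with an estimated correlation.

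The 12199 genes gave 9285 calls in controls (4080 higher, 5205 lower) and 25 in the knockout (17 higher, 8 lower), sharing 7 higher and 4 lower where independent calls would share 5.69 and 3.41 (one-sided Fisher p = 0.33 and 0.468). The count in the knockout was 172 without knockout zygote replicate 2, 11 without its replicate 1 and 43 without 48 h knockout replicate 2. Median-ratio rescaling moved the median of all genes to -0.073 in controls and to 0.087 in the test of the difference. Quantile normalization moved them to -0.256 and 0.23.

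**Figure D2:**
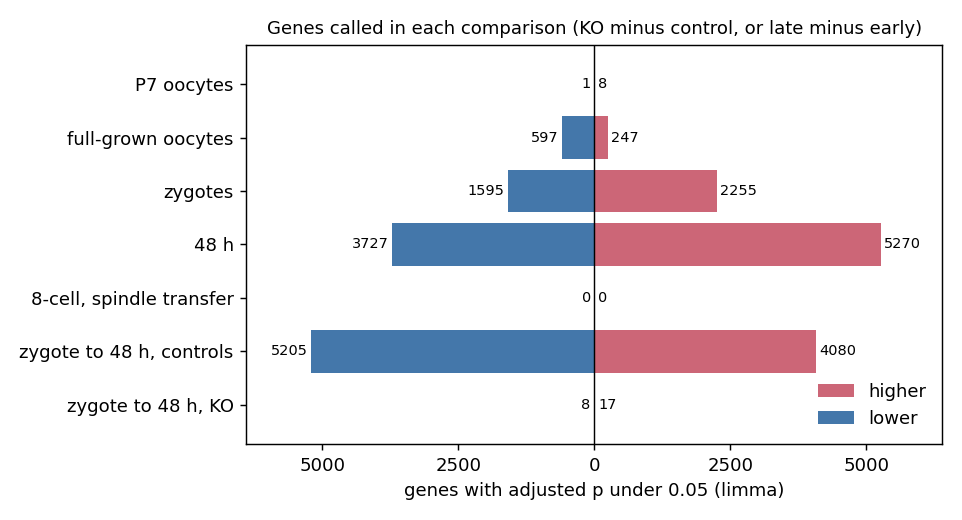
Genes called higher (right) and lower (left) by limma in each comparison, as bars of gene counts on a linear axis. The bars run from 0 in spindle-transfer embryos to 9285 for the change from zygote to 48 h in controls, against 25 for the same step in the knockout.

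**Figure D3:**
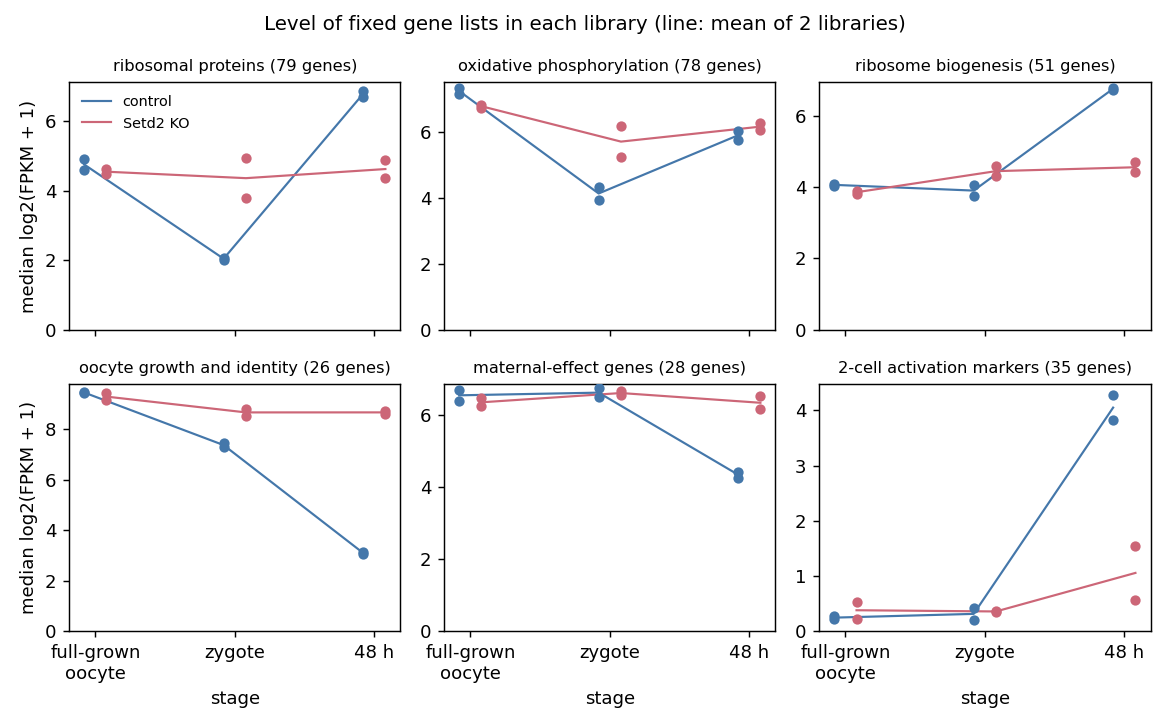
Median log2(FPKM + 1) of 6 gene lists in full-grown oocytes, zygotes and 48 h embryos, with a point for each library and a line through the mean of 2 libraries for controls and knockout. The oocyte identity list ends at 3.06 and 3.15 in control embryos and at 8.75 and 8.61 in knockout embryos.

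Spindle-transfer 8-cell embryos, in which the spindle and chromosomes of an egg were moved into the cytoplasm of another before sperm injection, had no gene called between those labelled -/- and +/-. Transfers in both directions are described and the labels do not say whether the genotype is that of the spindle or of the cytoplasm. The smallest p in the upward direction was that of Ftl1, the ferritin light chain, at 717 ± 2.69 against 237 ± 24.3 FPKM (limma adjusted p = 0.112), and in the downward direction that of Omt2a, an oocyte maturation gene, at 0.731 ± 0.576 against 23.1 ± 1.97 (limma adjusted p = 0.112). Sap30, a subunit of a histone deacetylase complex, stood at 47.2 ± 0.435 against 149 ± 15.7 (limma adjusted p = 0.127), and Dnmt3l at 68.4 ± 16.5 against 29.7 ± 8.75 (limma adjusted p = 0.229). As sets with a preset correlation, ribosomal proteins (median 0.44, adjusted p = 3.87e-14), oxidative phosphorylation (0.22, 0.00199), genes imprinted by H3K27 trimethylation (0.34, 0.011) and from maternally methylated regions (0.27, 0.0129) lay higher and 2-cell markers lower (-0.85, 0.011). None of their 79, 78, 15, 24 and 22 members was called over all genes, and adjusted over the list alone limma called 8, 1, 1 and 1 higher and 1 lower. The same lists had an adjusted p = 0.717, 0.738, 0.717, 0.717 and 0.717 with an estimated correlation. Limma called 0 of 9398 genes, with 1243 at an unadjusted p under 0.05, and called 49 without control replicate 1 and 29 without control replicate 2. On simulated data of this design, limma recovered 37% of 4-fold changes.

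Full-grown oocytes labelled Dnmt3l knockout were compared with their control by fold alone, since 1 library per group allows no test. The Dnmt3l transcript was 25 FPKM in the library labelled knockout and 31.7 in the control, so the label could not be checked from this transcript, and Setd2 was 3.52 and 3.6. Lower in the library labelled knockout were the steroid enzyme genes Hsd3b1, at 0.162 against 26.8 FPKM, and Cyp11a1, at 0.68 against 13.3, with Inha at 1.63 against 22.1, the Wnt inhibitor gene Sfrp4 at 0.00818 against 21.5 and the connexin gene Gja1 at 5.01 against 30.2. Cyp11a1 and Inha are on the list of granulosa and cumulus markers, and whether RNA of attached cells differed between the 2 libraries was not tested. Higher were Camk2g, a calcium-dependent kinase, at 103 against 31.2 FPKM and Igf2bp3, an RNA-binding protein, at 70.1 against 24.6. Of 4530 genes with 10 FPKM or more in the higher library, 30 were at least 2-fold higher and 26 at least 2-fold lower.

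Of the gene lists in the Dnmt3l pair, 9 granulosa and cumulus markers had a median of -1.12 (-2.873 with a pseudocount of 0.1 and -0.303 with 5), below those of all 10000 random lists of the same size at the pseudocount of 1. Some of these markers were higher in the library labelled knockout, Cyp19a1 at 22.1 against 16 FPKM, Nr5a2 at 5.91 against 3.88 and Serpine2 at 280 against 262, names chosen after their values were seen. The 79 ribosomal proteins had a median of -0.172, also below all of the random lists. DNA methylation genes lay at -0.251 (percentile 0.81 of random lists) and meiosis genes at 0.123 (percentile 99.3). The 180 measured genes called higher in Setd2 knockout oocytes had a median of 0.181 in the Dnmt3l pair (percentile 100) and the 555 called lower one of -0.047 (percentile 0.19). Random lists take genes as independent, which genes of a pathway are not, and the order of these values rests on a single library in each group.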

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

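Of the tests here, those that left out a zygote library, the mixtures of RNA, the count of paralog families and the count of granulosa markers were tests chosen only after the result was seen. The tests of transcript length and of scaling were written down before.

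The change from zygote to 48 h differed between genotypes for 8079 of 12199 genes by limma's test of the difference, and the Setd2 effect differed between zygotes and full-grown oocytes for 1145 genes. Both were singled out because an effect differs between groups. The first compares 1-cell knockout embryos with 2-cell controls, so genotype and cell stage cannot be separated.

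Ribosomal protein and oxidative phosphorylation transcripts were higher in knockout zygotes than in controls, with medians of 1.687 and 1.251. Transcript length bias is argued against as the whole cause, since the medians stayed at 1.191 (95% bootstrap interval 0.987 to 1.782) and 0.829 (0.555 to 1.207) after removal of the length and expression trend, although both fell. A single knockout library is argued against as well, since the medians were 1.324 for ribosomal proteins and 0.846 for oxidative phosphorylation without knockout replicate 2, although the second is weaker (lower quartile 0.075, 30 of 78 called). A mixture of zygote RNA with full-grown-oocyte RNA is not decided by the test made. As the whole cause it would bring every abundant oocyte transcript. The share read from falling genes was at least 0.311 in replicate 1 and 0.768 in replicate 2. Of 2927 genes with at least 20 FPKM in both knockout oocytes, 14 lay in both knockout zygotes under 50% of the level these shares would bring, 3 of them under 10%, against at most 3 of 3070 for the same drop between knockout zygotes and knockout 48 h embryos (one-sided Fisher p = 0.00478). The shares read from falling and rising genes were 0.334 and 0.317 in replicate 1, where they did not separate, and 0.801 and 0.579 in replicate 2. This was the last of 3 definitions, and the first 2 gave 0.356 against -2.398 and 0.368 against 0.454 in replicate 1, and 0.906 against 0.515 and 0.804 against 0.623 in replicate 2. The genes of the Fisher test are not independent, and its reference is another pair of stages. Most list members lay at or below the highest of the knockout oocyte and control zygote libraries, as a mixture allows. Above it in replicates 1 and 2 were 14 and 36 of 79 ribosomal proteins and 0 and 7 of 78 oxidative phosphorylation genes. The mixture stays open, as do RNA of unfertilized eggs, a stage the series lacks, and a delay of the knockout zygotes in losing egg transcripts. The last 2 may give such levels and were not tested.

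Of 39 markers of 2-cell activation, Zscan4 members included, 15 were at least 2-fold above both knockout zygotes in 48 h knockout replicate 2 and 0 in replicate 1, where some stood above them by less. The list median of log2(FPKM + 1) was 1.546 in replicate 2 and 0.566 in replicate 1, against 0.369 and 0.346 in knockout zygotes. Shares were read as the part of the way from the mean of the knockout zygotes to control 48 h replicate 2. They are not percents of the control level, and a gene already present in knockout zygotes can score low. The 6 Zscan4 members reached in knockout replicate 2 a median share of 56.77% (42.732 to 110.613). The 20 other markers reached 3.613% (1.097 to 8.678). The 1953 other genes that rise in controls reached 2.206% (1.901 to 2.51, 95th percentile 47.607%). Before the list was split, the 24 members that rise in control replicate 1 had a median share of 5.283% (1.445 to 20.977). Of these, 4 are Zscan4 members with a share of 62.332% (39.613 to 142.41). Admixture of control 2-cell RNA is argued against as the whole cause, since it would bring every abundant 2-cell transcript. Of genes to which the lower bounds of these shares would bring at least 5 FPKM and which were low in both knockout zygotes, 909 of 1000 lay under 50% of that level at the share of the Zscan4 members and 16 of 18 at that of the other markers. The same drop between the 48 h knockout replicates was seen for at most 505 of 6593 genes (one-sided Fisher p = 2.35e-16 for the 16). A smaller share stays open, and RNA of embryos at another point of the 2-cell stage was not tested. Of the 15 members 11 were also at least 2-fold above replicate 1. Reads shared within 1 family of paralogs are argued against as the sole source. The 8 of these 11 with names other than placeholders fell into 5 symbol stems, Zscan4 among them. Sharing inside each of several families is not decided by this count, since it would also give several stems. A start of the 2-cell programme in some embryos of this library may be a candidate explanation, resting on 1 library.

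Inha and Cyp11a1 were low in Setd2 knockout full-grown oocytes, with Inha at 14.8 and 15.1 FPKM in controls and 0.816 and 0.519 in the knockout. Fewer attached granulosa cells in the knockout samples could lower such markers: 13 of 26 were below both controls in both knockout libraries and 5 above, most at under 1 FPKM, while of the 5 with at least 1 FPKM in controls 2 were below and 3 above (Cyp19a1, Nr5a2 and Serpine2). Zygote libraries of both genotypes held these 3, Cyp19a1 at 13.1 to 20.1, Nr5a2 at 3.13 to 9.765 and Serpine2 at 286 to 468 FPKM. Inha and Cyp11a1 were at no more than 0.37 FPKM there. The 3 may thus be carried by the oocyte, and their rise does not tell against fewer attached cells. Whether oocytes carry Inha and Cyp11a1 was not tested, which leaves that explanation open. Both were also lower in the library labelled Dnmt3l knockout than in its control, Inha at 1.63 against 22.1 FPKM and Cyp11a1 at 0.68 against 13.3. Cyp19a1, Nr5a2 and Serpine2 were higher there, and that pair has 1 library per group. Fshr stood higher in Setd2 knockout oocytes, at 9.49 and 8.25 FPKM against 0.415 and 0.18. In knockout zygotes it stood at 3.08 and 4.18 FPKM, and it was listed at 0 in both control zygotes. Its rise may thus be carried by the oocyte too and does not tell against fewer attached cells. Scaling of the FPKM values between libraries is argued against, since the 2 markers called lower, Inha and Cyp11a1, stayed called after median-ratio scaling. A change in the oocyte itself stays open as a hypothesis and was not tested apart from the cells around it.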

How the results depend on the processing

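The zygote lists without single libraries, the list medians after quantile normalization and the step from full-grown oocyte to zygote were tests chosen only after the result was seen, and the other alternatives were planned. In growing oocytes limma called 9 genes, 0 without a filter (959 of 15372 at an unadjusted p under 0.05), 0 without a variance trend (825), 16 with a filter at 5 FPKM and 129 with a replicate block (54 higher and 75 lower in place of 8 and 1). In full-grown oocytes it called 844, 489 with a pseudocount of 0.1, 500 without a filter and 2787 with the compared groups alone. In zygotes it called 3850, and 2607 with the compared groups alone, so the order of these stages turned. In spindle-transfer embryos it called 0 (1243 at an unadjusted p under 0.05) and 15 with a replicate block. For the step from zygote to 48 h in the knockout it called 25, 9 with a pseudocount of 5, 40 without a filter and 5 with the compared groups alone. The difference between zygotes and full-grown oocytes gave 1145, and 603 without a filter. The cause was not tested in any of these, except that a filter changes how many genes are adjusted together. The spread between replicates, shared in the fit of 12 libraries, was smallest in full-grown oocytes. The SD of the log2 difference was 0.331 and 0.34 there, against 0.444 to 0.577 in the other groups of that fit. Of the Dnmt3l folds, 56 passed 2-fold with a pseudocount of 1 and 22 with 5, since a larger pseudocount shrinks folds by construction.

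Leaving out each library in turn gave 5 to 16 genes in growing oocytes, 43 to 145 in full-grown oocytes, 2256 to 3935 in zygotes, 7142 to 8340 at 48 h, 0 to 49 in spindle-transfer embryos, 11 to 172 for the 48 h step in the knockout, 320 to 1964 for zygotes against full-grown oocytes, and 3146 to 4322 in controls and 313 to 2885 in the knockout for the step from oocyte to zygote. Each such fit leaves 1 library in a group, which is assumed to vary like the other groups. Of 474 named calls, 395 held in every one of them, 15 of 61 in full-grown oocytes, 78 of 103 in zygotes and 106 of 107 at 48 h, and 450 held with a pseudocount of 0.1 and 468 with 5. Changes that turned direction were all of genes with no call: Setd2 in spindle-transfer embryos was 0.042 after quantile normalization and -0.188 to 0.031 without single libraries, Setd2 in the knockout from zygote to 48 h was -0.041 after quantile normalization and -0.084 to 0.16 without single libraries, with -0.05 without 48 h knockout replicate 2, and Dnmt3l there was -0.22 to 0.319, with -0.038 without 48 h knockout replicate 1.

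Of 40 list calls in the planned contrasts, 0 held with an estimated correlation. How well these libraries estimate that correlation was not tested. The overlaps of calls between full-grown oocytes and zygotes, and of higher calls between zygotes and 48 h, kept a one-sided Fisher p under 0.05 with genes called at an adjusted p of 0.1. Simulated 2-fold changes were recovered in 28% of cases in zygotes, where the smallest library had 3.13 M fragments (M for mega) by the approximate estimate, and in 0% in spindle-transfer embryos.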

Other observations

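The tests of the step from full-grown oocyte to zygote, the sets chosen in a control replicate, the genes of the 48 h knockout embryos and the X-linked shares were tests chosen only after the result was seen. From full-grown oocyte to zygote, ribosomal protein and respiratory transcripts fell in controls, and in the knockout respiratory ones fell less and ribosomal protein ones fell in 1 of the replicates. Across genes the change went with transcript length (Spearman correlation 0.388 in controls, 0.371 in the knockout). Genes that fell had a median of 2176 and 1796 nt, and those that rose 4240 and 4403 nt. Both lists are short (1059 and 1025.5 nt), and no length correction was made for this step. Of 79 ribosomal protein genes, 66 fell and 1 rose in controls (67 and 1 adjusted over the list alone), against 14 and 1 in the knockout (18 and 2 adjusted over the list alone), with medians of -2.42 and -0.38 relative to all genes. Of 78 genes of oxidative phosphorylation, 67 fell and 1 rose in controls (69 and 1 adjusted over the list alone), against 33 and 1 in the knockout (38 and 2 adjusted over the list alone), with medians of -2.35 and -0.96. The difference between genotypes in this step is the test of the Setd2 effect in zygotes against oocytes given above. Both lists passed there with a preset correlation and not with an estimated one. The knockout zygotes differed: the median log2(FPKM + 1) of ribosomal proteins was 4.48 and 4.609 in knockout oocytes, 3.778 in zygote replicate 1 and 4.939 in replicate 2, so their fall was in 1 library, and that of oxidative phosphorylation was 6.828 and 6.744, then 5.239 and 6.184. As sets in limma's camera these had an adjusted p = 1.25e-19 and 2.26e-21 in controls (0.413 with an estimated correlation) and 5.73e-05 and 1.3e-15 in the knockout (adjusted p = 0.658 with an estimated correlation). RNA decay and storage genes gave 13 higher and 2 lower of 26 in controls (15 and 2 adjusted over the list alone) and 11 and 1 in the knockout (12 and 1 adjusted over the list alone). Limma called 5190 genes in controls, 2260 higher, and 2154 in the knockout, 1532 higher, of which 441 fell in both where independent calls would share 149 (one-sided Fisher p = 6.2e-143). The median of all genes was -0.06 in controls and 0.117 after quantile normalization, which gave 3179 higher and 2435 lower genes in place of 2260 and 2930. In the knockout, median-ratio rescaling gave 961 higher and 1153 lower (45.5% higher in place of 71.1%) and quantile normalization 57.4% higher. The count was 3146 in controls without control oocyte replicate 2, and in the knockout 313 and 868 without oocyte replicates 1 and 2 and 624 without zygote replicate 1.

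Genes chosen by their change of at least 2 in log2 in control replicate 1 were read in the other libraries. The 788 genes that fell from oocyte to zygote had a median of -2.735 in control replicate 2, of -1.196 in knockout replicate 1 and of -0.246 in knockout replicate 2, while the 184 that rose had medians of 1.315, 1.354 and 0.996. The 2018 that rose from zygote to 48 h had a median of 3.383 in control replicate 2, and of 0 and 0.279 in the knockout, and the 2231 that fell had medians of -2.952, -0.054 and -0.093.

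Several of the 25 genes called from zygote to 48 h in the knockout were high in knockout oocytes, low in knockout zygotes and high again at 48 h, with names chosen after their values were seen. Prss30 stood at 6.92 and 4.82 FPKM in knockout oocytes, was listed at 0 in both knockout zygotes and stood at 8.08 and 8.2 at 48 h, a rise of 3.19 (limma adjusted p = 0.000423). Scimp, an adaptor of immune cells, went from 41.3 and 43.6 to 1.25 and 0.661 and then to 35.1 and 27 FPKM (4.04, limma adjusted p = 0.00227). The low zygote value was not particular to the knockout: in controls Scimp went from 7.75 and 15.2 to 0.616 and 0.682 FPKM, and Amd1 from 29.5 and 30.1 to 0.36 and 0.186. Prss30 and Dcpp1 did not go this way in controls, where they stayed at no more than 1.45 and 2.11 FPKM. Amd2, the near-identical paralog of Amd1, went the other way in controls, from 0.0165 and 0.00902 in oocytes to 56.1 and 49.3 FPKM in zygotes. From zygote to 48 h in the knockout, Amd1 changed by 5.31 and Amd2 by -5.41. Reads may be divided between them, so the low zygote value of Amd1 is uncertain. Dcpp1 stood at 24.3 and 20.1 FPKM, was listed at 0 in both knockout zygotes, and stood at 26 and 7.74 at 48 h (limma adjusted p = 0.00534, uncertain for reads shared with its paralogs). Hormad1, low in knockout oocytes at 0.314 and 0.111 FPKM, stood at 19.6 and 4.33 at 48 h, against 67.4 and 83.4 in controls (3.26, limma adjusted p = 0.0344).

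Of the genes called lower in full-grown knockout oocytes, 37 of 590 with a known chromosome were X-linked (6.27%), against 371 of 11418 other genes (3.25%, two-sided Fisher p = 0.000391, and 0.000141 with 1 X-linked gene per symbol stem). Only X-linked genes were reduced to stems, so such values thin 1 side of the comparison and do not correct for gene families. Among the genes called higher there, 8 of 242 were X-linked (3.31%, two-sided Fisher p = 1). In zygotes 80 of 1562 genes called lower were X-linked (5.12% against 3.14%, two-sided Fisher p = 0.000126) and 54 of 2223 called higher (2.43%, two-sided Fisher p = 0.0043, and 0.154 with 1 X-linked gene per symbol stem). At 48 h 142 of 3672 genes called lower were X-linked (3.87% against 3.19%, two-sided Fisher p = 0.063, and 0.0176 with 1 X-linked gene per symbol stem) and 164 of 5189 called higher (3.16% against 3.58%, two-sided Fisher p = 0.222).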
